A study of Mus musculus with 12 samples.

How the data were processed

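Per the labels' protocols, T cells were sorted from dissociated tumors, polyA RNA was made into strand-specific libraries, and read pairs of 150 bp were sequenced. Per the submitters' processing notes, HISAT2 2.1.0, featureCounts and DESeq2 1.38.0 were used, with the GRCm38 or mm10 assembly. Per the file headers, featureCounts 2.0.0 counted read pairs over exons joined by gene in a refGene annotation of mm10. It counted only pairs with both ends mapped and a fragment length of 50 to 600 bp, with the strand setting 2, which is reverse-stranded. The deposited values are therefore raw counts per gene, which were not used here.

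All 12 count columns match no sample label, and they were left out of every step. Their names hold a running number that occurs in no title, description or characteristic. Giving the numbers to samples by their order would have been a guess. The tests fixed before the data were examined, edgeR's quasi-likelihood test among them, were not run. With a record that ties the column names to the samples, they could be run as fixed where the table lists enough of the genes they use. A gene list test needs only a fixed minimum of tested members, not every symbol of the list. The table lists 0 of the 13 symbols of mitochondrially encoded genes, so no test of that list could be run.

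Gene symbols, exon positions and exonic lengths, which belong to no sample, were read with Python 3.11.15 and pandas 2.3.3. A gene's start and end are the lowest start and highest end of its exons in the deposited table, counted from 1. Gene list symbols were matched to the table's symbols exactly, so a symbol counts as not listed where the table has the gene under another symbol. A second count, chosen after seeing the data, also matched synonyms in a RefSeq gene table of GRCm38.p6. It is named where used.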

Results

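RNA was sequenced from CD8+ T cells sorted out of B16 tumors, a transplantable mouse melanoma, grown for 14 days in wild-type mice. The tumor cells, not the T cells, carried the genetic change. The 4 tumor genotypes were a scramble control (Scram), Lsd1 knockout (Lsd1 KO), the Tgfb knockout called TKO, and the Lsd1 and Tgfb knockout called QKO. Each genotype had 3 libraries, 12 in all, and each library pooled the T cells of 2 tumors, with about 30000 to 70000 sorted cells.

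The design implies 3 comparisons of a knockout with Scram, the comparisons of QKO with Lsd1 KO and with TKO, and the interaction of Lsd1 and Tgfb loss. None of these comparisons was made. The 12 count columns of the deposited table carry names that match no sample label used here, so no column was given to a genotype. No expression level, depth per library, fold change or p-value is therefore reported, and nothing here bears on whether T cells differed between the tumor genotypes.

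The columns of the table that belong to no sample describe 25239 genes of the mouse mm10 assembly, with a median exonic length of 2259 bp. Lsd1 is encoded by Kdm1a, a histone demethylase gene, which lies on chromosome 4 from 136550533 to 136602723 on the minus strand, with 3087 bp of exons. Of the TGF-beta ligand genes, Tgfb1 lies on chromosome 7 from 25687002 to 25705077 on the plus strand, with 2175 bp of exons. Tgfb2 lies on chromosome 1 from 186622792 to 186705989 on the minus strand, with 5200 bp of exons. Tgfb3 lies on chromosome 12 from 86056743 to 86079041 on the minus strand, with 3385 bp of exons. The labels used here do not say which ligand genes TKO tumors lack. The T cells were of wild-type mice, so a count of these genes in T cells would not check the tumor genotype.

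The table lists 743 of the 779 gene symbols in 29 lists fixed before the data were examined. Some lists hold an older and a newer symbol of the same gene, so a symbol not listed is not always a missing gene. All 24 cytotoxic effector symbols, such as the granzyme gene Gzmb and the perforin gene Prf1, are listed, as are all 54 cell cycle symbols. Fewer are listed for NK and gamma-delta T cell markers, 9 of 17, and for B cell and plasma cell markers, 11 of 18. Both counts stay the same with RefSeq synonyms. Of the 24 symbols of inhibitory receptors and exhaustion, 23 are listed exactly and all 24 when RefSeq synonyms are also matched. Cd244 and Cd244a, both in that list, are symbols of the same gene, so the synonym match need not add a gene. None of the 13 symbols of mitochondrially encoded genes is listed under the names used or under their RefSeq synonyms.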

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

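No comparison was made, so none of the alternatives fixed before the data were examined was run. The only values that could be recomputed are the numbers of gene list symbols in the table, in all and per list. The total went from 743 with exact symbols to 748 when synonyms in a RefSeq gene table of GRCm38.p6 were also matched. This setting was chosen after seeing the data. Counts rose for hypoxia (26 to 28), oxidative phosphorylation (76 to 77), inhibitory receptors and exhaustion (23 to 24) and the interferon-gamma response (33 to 34). These are counts of symbols, and a rise need not add a gene. The hypoxia list holds both Ero1l and Ero1a, and both Ak4 and Ak3l1, which are alternative symbols. The same holds for Cd244 and Cd244a in the exhaustion list, and for Wars and Wars1 in the interferon-gamma list. No paired analysis was possible because the count columns match no sample label and carry no replicate number of the labels. The labels also name no batch or pairing of libraries across genotypes.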
